A study of Drosophila melanogaster with 3 samples.

How the data were processed

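Per the labels, 3 biological replicates of embryos from the Dad-GFP line were immunoprecipitated with an antibody against GFP and sequenced; fragmentation was by sonication, with sizes of 200 to 800 bp. All 3 form 1 group, so replicates were used only to measure agreement and spread. Each label gives a biological replicate number, and the replicates are numbered here accordingly.

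The deposited files are peak lists in narrowPeak form, on builds dm6 and dm3. Per the file listings, the authors called 30000 regions (peaks and background as input for IDR) on each replicate and on the 3 alignments pooled, in each case against a control alignment, and derived from them an optimal list of peaks that passed an IDR threshold. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The control library is not analysed here. Per the file listings, the deposited signal column holds the caller's signal value for a region; it is not scaled between libraries, so it was used only to rank and filter within a list, and replicates were compared after division by the median over the optimal peaks. The deposited −log10 q values reached a ceiling (3.87 in the pooled and optimal lists) and were not used for ranking. The deposited column of summit positions gives the distance in bp from the region's start; in 3 optimal peaks it lay past the region's end and the last base was taken. A pair of optimal peaks shares 1 set of coordinates, and both were kept. Because no read counts are in these files, depth is unknown and its effect on precision could not be measured; a list of fixed length holds more background where depth is lower. The numbers of regions with a −log10 q of at least 2 were 3927, 6376 and 6410 in replicates 1, 2 and 3.

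The dm6 lists were joined to the Ensembl annotation, release 115 (BDGP6.54), and to the RefSeq sequence of the same assembly. No region ended beyond its arm (3R is 32079331 bp long, and the last region on it ends at 32069875). Pseudogenes and transposable elements were left out, which leaves 13945 protein-coding and 3951 other genes on the 6 arms. Lists defined by the start of a symbol take in relatives, such as RpLP0-like among the ribosomal proteins. No genome of build dm3 was used, so the dm3 lists were only counted and compared with one another. Of the listed gene symbols, 3 were matched through older names (phl to Raf, Dl to Delta and h to hry).

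Replicate support was the share of optimal peaks overlapped by at least 1 bp by the 3392 regions of highest signal in a replicate, as many as there are optimal peaks, with 100 random placements within arms for comparison. A summit was assigned to 5′ UTR, coding sequence, 3′ UTR, other exon, intron or intergenic in that order of priority, and separately to TSSs within 500 bp. Peaks were compared with the 25850 pooled regions that overlap no optimal peak by Fisher's exact test, two-sided. Random positions were 10 per peak on the same arm. Odds ratios carry Woolf 95% intervals, and single shares carry Wilson intervals, which cover counting error only. For gene lists, the number of genes with a summit within 500 bp of a TSS was tested by an exact permutation test, in which list membership is redrawn within 10 classes of gene length among genes of the same type (coding or not); the p-value doubles the smaller tail. Motifs and 6-mers were searched on both strands within 100 bp of the summit, with 1 background region per peak drawn from the same decile of GC content and the same TSS class. GC content was 38.6% at peaks, 46.2% in all background regions and 38.9% in the matched ones. Benjamini-Hochberg adjustment was made over the 7 location classes, the 20 gene lists, the 20 motifs and the 2080 6-mers, each with a threshold of 0.05. Medians of signal were compared by a permutation test with 100000 resamples, and the Dad window with 1000 random windows on its arm.

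Genes are named by a rule fixed in advance: the gene with the nearest protein-coding TSS to each of the 25 peaks of highest signal that all 3 replicates support, each member of the BMP pathway and Dpp target lists with a promoter peak, the strongest members of the other lists, and Dad. Genes of these lists that lack a peak, and those named for a peak in the gene body, were chosen after their values were seen. Assigning a peak to the nearest TSS does not show that it acts on that gene, and 1 peak between divergent genes counts for both.

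Alternatives tried were other overlap rules and region numbers, the dm3 lists, windows of 250 and 1000 bp around TSSs, random positions as background, the stronger 1696 peaks alone, other gene classes and peak-to-gene rules, motif windows of 50 and 250 bp, unmatched and flanking background, and leaving out each replicate in turn. Without 1 replicate, the optimal list was replaced by the top regions that the others share (2301, 2391 and 2285 regions without replicates 1, 2 and 3). Further draws of the motif background and 20 further gene lists were added after the data were seen.

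Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The tests were tested on simulated data. For the gene list test on 13945 genes, 200 simulated lists of 40 genes gave p below 0.05 in 2% where no list effect was planted and in 100% with a 3-fold share of peaks. The motif test on 1000 sequences gave 0% of 20 without and 100% of 20 with a motif planted in 5% of them, and the test of medians gave 6% of 100 with no difference and 100% of 100 with a 1.3-fold difference, on 500 values. Overlap counts equalled those of bedtools 2.31.1.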

Results

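Chromatin from whole Drosophila melanogaster embryos aged 0 to 24 h, with both sexes pooled, was immunoprecipitated with an antibody against GFP. The embryos came from a transgenic line that stably expressed the protein Dad with GFP fused to its C terminus. Dad (Daughters against dpp) is the inhibitory Smad of the fly, which restrains signalling by the BMP ligand Dpp and is itself a target gene of that pathway. Sonicated fragments of 200 to 800 bp were sequenced from 3 biological replicates, which form 1 group, so no comparison between groups exists and the replicates supply the error. The files hold 30000 regions for each replicate, 30000 regions called on the pooled alignments, and an optimal list of 3392 peaks that passed the authors' test of reproducibility between replicates (irreproducible discovery rate, IDR). Read depth is unknown, because the files give regions and signal values but no read counts. Coordinates are those of genome build dm6, and the question was where in the genome the tagged protein was recovered and at which genes.

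The 3392 optimal peaks lay on all 6 chromosome arms and covered 1255 kb, or 0.938% of their 133.9 Mb. Their signal, the authors' value per peak, ran from 80.7 to 1827 with a median of 121.7, and their median width was 410 bp. Density was similar on the 5 large arms, from 24.2 peaks per Mb on 3L (95% exact Poisson interval 22.4 to 26.1) to 27 on 2L (25 to 29.2). The small, largely heterochromatic chromosome 4 held 11 peaks, or 8.16 per Mb (4.07 to 14.6), and it also held fewer of the 30000 pooled regions, 118.7 per Mb against 212.3 to 230.2 on the other arms. These intervals cover counting error only. Every optimal peak carried the highest −log10 q value of its list, 3.87, so peaks were ranked by signal and not by q.

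Strong peaks ranked among the top regions of every replicate, while most weak ones fell below that rank in at least 1. Each replicate's 3392 regions of highest signal overlapped 81.3%, 77.6% and 83.3% of the optimal peaks in replicates 1, 2 and 3, a mean of 80.8% ± 2.90 (SD, n = 3), while random placement of the same regions gave at most 2.74%. The optimal peaks were derived from these same replicates and kept for reproducibility between them. Overlap well above random placement was thus built in, and it is no independent test of the peaks. All 3 replicates shared 1933 of the peaks (57.0%), and 15 peaks were in none of the 3 sets. Of the 848 peaks with the highest signal, 99.3% were shared by all 3 replicates (Wilson 95% interval 98.5 to 99.7). That share was 85.3% (82.7 to 87.5) in the next 848, 36.3% (33.2 to 39.6) in the 848 after these, and 7.08% (5.54 to 9.0) in the weakest 848. A requirement of 50% reciprocal overlap lowered the share common to all 3 replicates to 44.0%, and use of all 30000 regions per replicate raised it to 99.2%. Across regions matched between replicates, which are not independent of one another, Spearman's rho of the signal was 0.647, 0.661 and 0.638 for the 3 pairs. These values cover only the 31.3%, 32.5% and 33.2% of the 30000 regions that were matched in each pair. The coefficient of variation of a peak's signal between replicates, after division by each replicate's median over the optimal peaks, had a median of 23.1% over 3365 peaks.

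**Figure D1:**
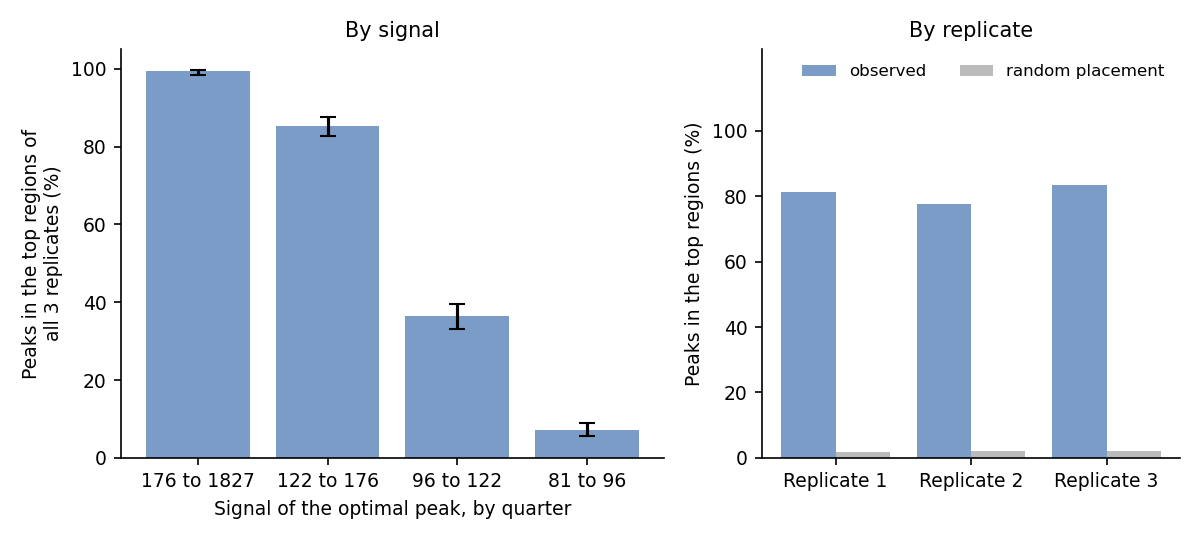
Left, share of optimal peaks (percent) overlapped by the top 3392 regions of all 3 replicates, in 4 classes of 848 peaks by signal, with Wilson 95% intervals. Right, share overlapped by the top regions of each replicate beside the mean of 100 random placements. Shares fall from 99.3% in the strongest class to 7.08% in the weakest.

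The genes with the nearest protein-coding TSS to the highest signals were of varied function. The strongest peak (X, 2703677 to 2704082) had a signal of 1827 and its summit lay 25 bp from the transcription start site (TSS) of Ugalt (FBgn0024994), a nucleotide-sugar transporter. Its signal relative to each replicate's median was 14.0 ± 1.54 (SD, n = 3). The next peak (2L, 480878 to 481302, signal 1745, relative signal 13.4 ± 0.646) lay in an intron of ush, 1371 bp from the TSS of cbt (FBgn0043364), a zinc finger transcription factor gene nested in ush. Peaks at CG14100 (3L, 19590424 to 19590812, signal 1673), px (2R, 22514102 to 22514503, signal 1514), which acts in wing vein patterning, and CG11050 (2L, 6612465 to 6612914, signal 1454) came next, with relative signals of 13.0 ± 1.21, 11.7 ± 0.787 and 11.2 ± 0.778. All 5 ranked within the top 5 regions of each replicate. The remaining 20 of the 25 highest peaks had signals of 739.2 to 1284. Chromatin regulators among them were Chro (1284), ph-p of the Polycomb group (1125) and osa of the BAP remodelling complex, whose TSS lay 13949 bp from its peak (741.6). Genes of translation and RNA were PNPase (1179), Lk6, a kinase of the initiation factor eIF4E (1155), larp (874.3), mRpL41 (859.5) and mRpL23 (739.2), the last 2 encoding proteins of the mitochondrial ribosome. The others were CG1888, CG9663, Art3, CenG1A, CG32772, tara, CG13921, CG13323, GstE13, Atat, Sox14 and Tlk. Some of these TSSs were far from the summit, at 3148 bp for tara, 11978 bp for CG13323 and 2319 bp for Tlk. A noncoding TSS lay nearer to the osa peak (lncRNA:CR46035, 706 bp) and to the tara peak (lncRNA:CR45643, 892 bp). Of these 25 peaks, 16 had their summit within 500 bp of an annotated TSS.

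Peaks concentrated at promoters and avoided coding sequence. A summit lay within 500 bp of an annotated TSS in 2075 of the 3392 optimal peaks (61.2%), against 28.9% of the 25850 pooled regions that overlapped no optimal peak and 13.8% of random positions. The odds ratio against the pooled regions was 3.88 (95% interval 3.6 to 4.18, Fisher's exact test, two-sided, adjusted p = 2.48e-289). In the top regions of the replicates the share was 60.9% ± 1.13 (SD, n = 3). The median distance to a TSS was 213 bp for peaks and 1303 bp for the other pooled regions. Only 18 summits (0.531%) lay in coding sequence, against 25.9% of the other pooled regions (odds ratio 0.0152, interval 0.00958 to 0.0242), and the replicate mean was 1.57% ± 0.845 (SD, n = 3). By contrast, intergenic summits made up 42.1% of peaks against 21.6% (odds ratio 2.63, 2.44 to 2.83, exact adjusted p = 1.79e-135), and 5′ UTR summits 13.9% against 9.25% (odds ratio 1.58, 1.42 to 1.76, exact adjusted p = 8.40e-16). Summits in 3′ UTRs were less frequent, 1.27% against 2.61% (odds ratio 0.479, 0.351 to 0.653, exact adjusted p = 4.69e-07). Introns held 39.6% of peaks and 38.2% of the other regions, a difference that did not pass the test (exact adjusted p = 0.150). Of random positions, 17.0% lay in coding sequence, 30.9% were intergenic, 3.49% in 5′ UTRs, 4.78% in 3′ UTRs and 42.3% in introns. The other pooled regions thus held more coding and fewer intergenic summits than random positions, which moves those 2 odds ratios farther from 1.

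Promoter peaks were not clearly stronger than the rest. Their median signal was 122.9, against 119.8 for the 1317 peaks farther than 500 bp from a TSS, a difference of 3.15 (permutation test, two-sided, p = 0.181). With a window of 250 bp the difference was −0.024 (permutation p = 1). With each replicate's own signal it was 3.80 in replicate 1 (p = 1e-05, the smallest that the 100000 resamples can give), 1.17 in replicate 2 (permutation p = 0.124) and 2.20 in replicate 3 (permutation p = 0.0472).

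Among 20 gene lists fixed before the data were examined, those of highly transcribed housekeeping genes carried promoter peaks far more often than genes of the same length, and chemoreceptor genes far less often. Of 13945 protein-coding genes, 2562 (18.4%) had an optimal peak summit within 500 bp of a TSS. For the cytoplasmic ribosomal proteins the number was 66 of 92 genes (71.7%, Wilson 95% interval 61.8 to 79.9), where gene length predicted 14.4%, a ratio of 5.0 (exact permutation test within length deciles, adjusted p = 2.37e-35). The ratio computed from each replicate's top regions was 5.10 ± 0.444 (SD, n = 3). The strongest of these promoter peaks were at RpL7 (2L, 10200880 to 10201165, 5′ UTR, signal 628.1, relative signal 4.89 ± 1.06, n = 3), RpS27 (3R, 25247389 to 25247673; 613.5; 4.82 ± 1.03) and RpL23A (3L, 1668625 to 1668905; 528.7; 4.03 ± 0.844). All 3 replicates shared 56 of the 66 peaks. In the list of translation factors, cytoskeleton and glycolysis genes, 11 of 15 had a promoter peak (73.3%, 48.0 to 89.1, 24.0% predicted, ratio 3.06, adjusted p = 9.10e-04, exact), and the replicate ratio was 3.07 ± 0.0490 (SD, n = 3). Its strongest were the glycolytic genes Gapdh2 (479.7) and Eno (244.2), the chaperone gene Hsp83 (357.2) and the elongation factor gene eEF1alpha1 (218.5), and all 11 were shared by the 3 replicates. This second call did not hold when any summit in the gene body or within 5 kb counted (ratio 1.5, exact adjusted p = 0.248). Odorant and gustatory receptor genes, which few sensory neurons use, had a promoter peak in 1 of 119 (0.840%, 0.148 to 4.61, 16.7% predicted, ratio 0.0503, exact adjusted p = 1.32e-07), and the replicate ratio was 0.0344 ± 0.0298 (SD, n = 3). The exception was the carbon dioxide receptor gene Gr63a (signal 91.4), and without replicate 1 or without replicate 3 the count was 0 of 119.

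**Figure D2:**
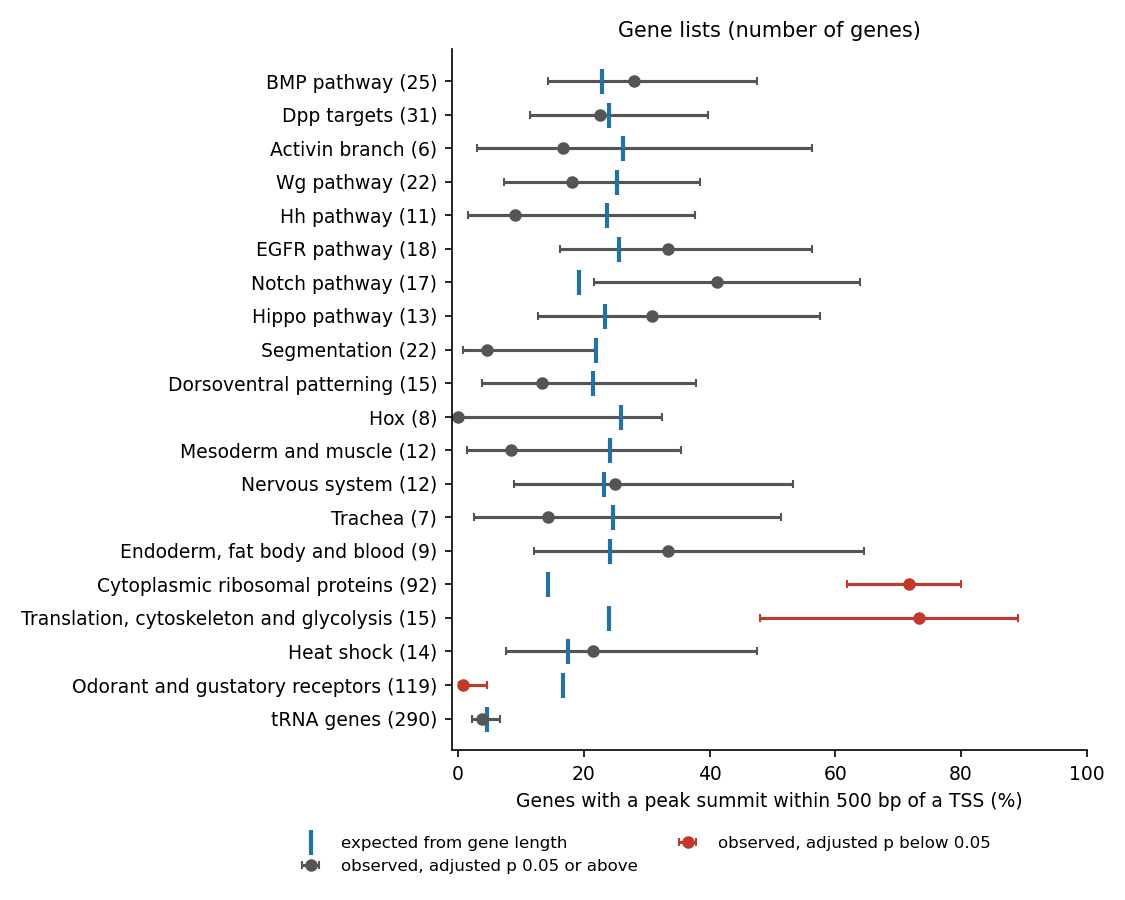
Share of genes (percent) with an optimal peak summit within 500 bp of a TSS in each of the 20 lists, as points with Wilson 95% intervals, beside the share predicted from gene length (bars). Ribosomal protein genes (71.7%) and the list of translation, cytoskeleton and glycolysis genes (73.3%) lie above their prediction, and odorant and gustatory receptors (0.840%) below.

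The pathway in which Dad acts did not stand out at promoters. In the BMP pathway list, 7 of 25 genes had a promoter peak (28.0%, Wilson 95% interval 14.3 to 47.6), against 22.9% predicted (ratio 1.22, exact adjusted p = 1), and the replicate ratio was 1.40 ± 0.176 (SD, n = 3). These were magu (2R, 10056459 to 10056606, intron, signal 280.4, relative signal 2.13 ± 0.290, n = 3), which encodes a secreted BMP modulator, shn (2R, 11173439 to 11173548, intron; 226.1; 1.90 ± 1.15), the zinc finger partner of Mad and Medea, the kinase gene nmo (139.9; 1.11 ± 0.274), Dad itself (127.2; 1.08 ± 0.258), the extracellular regulator cv-2 (101.7; 0.864 ± 0.354), and the glypican genes dlp (96.6; 0.862 ± 0.448) and dally (86.9; 0.798 ± 0.236). When any summit in the gene body or within 5 kb counted, 18 of the 25 had a peak (72.0%) where 50.6% was predicted (ratio 1.42, exact adjusted p = 0.151). No peak of that kind was found at tkv, put, scw, tsg, tld, tok or mav, which include the type I receptor gene tkv and the type II receptor gene put. Among genes with a peak by this rule only, the ligand gene dpp had an intronic peak (2L, 2433428 to 2433837, signal 183.4), the receptor-activated Smad gene Mad an intronic one (signal 275.0) and the co-Smad gene Med an intergenic one (3R, 31616039 to 31616345, signal 524.4). The counts of 7 and 18 both include Dad, the tagged gene, where extra copies of the locus in the transgene could add reads.

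Genes known to respond to Dpp did not differ from the prediction by the test at promoters. A promoter peak was found at 7 of 31 (22.6%, 11.4 to 39.8, 23.9% predicted, ratio 0.943, exact adjusted p = 1), with a replicate ratio of 0.678 ± 0.244 (SD, n = 3). They were Dll (150.7), ush (135.7), Dad (127.2), tin (102.8), rho (95.5), peb (93.8) and bi (83.8), all below a signal of 151. The promoter peaks of Dll, ush and Dad were shared by the 3 replicates, that of peb was in 2 and those of tin, rho and bi were in 1. Dad is the tagged gene, and extra copies of its locus in the transgene could add reads there. With the smaller sets of regions shared by the other replicates, 3 of 31 had a promoter peak whichever replicate was left out. The ratio was then 0.595, 0.567 and 0.567 without replicates 1, 2 and 3 (exact adjusted p = 0.741, 0.775 and 0.790). With the gene body rule, 16 of 31 had a peak (51.6%, 52.4% predicted, exact adjusted p = 1). The strongest by this rule were at ush (1745, rank 2, the peak named above for cbt), bam (613.5, the promoter peak of RpS27), Ance (464.2) and Dad (400.3). The peak counted for Ance lay outside that gene, in a 5′ UTR of another. The genes without a peak included salm, salr, vg, pnr, zen, C15 and bap. The gene brk, the repressor that Dpp signalling turns off, had 1 within 5 kb but outside the gene (signal 157.0).

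None of the remaining signalling and patterning lists passed the test at promoters. Promoter peaks were found in 7 of 17 Notch genes (41.2%, 19.2% predicted, exact adjusted p = 0.246), led by E(spl)m7-HLH (122.7), neur (119.6) and mib1 (112.2). The Notch ratio of 2.15 was not stable: it was 1.75, 0.428 and 1.24 without replicates 1, 2 and 3, with 1 of 17 genes left without replicate 2, and 0.557 among the stronger 1696 peaks. Promoter peaks were also found in 6 of 18 EGFR pathway genes (spi 377.7, Krn 204.5 and Ras85D 153.2), 4 of 13 Hippo genes (hpo 204.8, kibra 202.7 and Mer 199.9), 4 of 22 Wg pathway genes (sgg 387.6, nkd 95.5 and Wnt6 93.9), 1 of 11 Hh pathway genes (ptc, 81.2) and 1 of 6 genes of the Activin branch (Fs, 94.2), each with an exact adjusted p of 1. Segmentation genes had 1 promoter peak in 22 (bcd, 162.2; 4.55% against 21.9% predicted, exact adjusted p = 0.246). By the gene body rule 4 of the 22 had a peak (18.2%), fewer than the 48.2% predicted (exact adjusted p = 0.0339). None of the 8 Hox genes had a promoter peak (Wilson upper limit 32.4%, exact adjusted p = 0.600). The counts were 2 of 15 for dorsoventral genes (ush 135.7 and rho 95.5) and 1 of 12 for mesoderm and muscle (tin, 102.8). Nervous system genes had 3 of 12 (elav 374.4, scrt 109.4 and pros 95.9), tracheal genes 1 of 7 (bnl, 173.7), and endoderm, fat body and blood genes 3 of 9 (fkh 226.4, ush 135.7 and Hnf4 132.7). Heat shock genes had 3 of 14 (Hsp27 414.1, Hsp83 357.2 and Hsp26 134.1), and the exact adjusted p of these 6 lists lay between 0.994 and 1. Of 290 tRNA genes, 11 had a peak (3.79%, 4.53% predicted, exact adjusted p = 1), led by tRNA:Tyr-GTA-1-8 (455.4) and tRNA:Phe-GAA-1-2 (246.9), whose peak is also the promoter peak of RpL17. Besides Notch, 3 of these lists changed direction without 1 replicate, none past the threshold: EGFR without replicate 1 (ratio 0.955 against 1.3), and nervous system (0.988 against 1.08) and tRNA genes (1.16 against 0.837) without replicate 2. With the gene body rule the tRNA share was 24.1% against 31.5% predicted (exact adjusted p = 0.00425).

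The Dad locus, whose gene product was tagged, carried more peaks than most of its chromosome arm. Dad (FBgn0020493) spans 3R, 17054007 to 17070408, on the plus strand. Within the gene and 50 kb on either side lay 12 optimal peaks, where 1000 random windows of that width on 3R had a median of 3 and 10 of them held as many. The top regions of replicates 1, 2 and 3 numbered 12, 12 and 11 in this window, more than in all but 14, 14 and 19 of the random windows. The 5 optimal peaks inside Dad comprised 1 in the 5′ UTR (17053859 to 17054268, signal 127.2) and 4 in introns. The strongest of these (17065010 to 17065273) had a signal of 400.3 and rank 133, and overlapped regions of signal rank 363, 116 and 88 in replicates 1, 2 and 3. It also overlapped another of the intronic peaks (17065187 to 17065596, signal 82.2). Downstream of the gene, peaks at 17072518 to 17072927 (158.9, at the promoter of mRpS11) and 17080576 to 17080985 (205.9, intronic) were among the top regions of all 3 replicates as well. The second of these overlapped a further peak (17080784 to 17081193, 153.7). Overlapping peaks were counted as separate, so the 12 are not all distinct stretches. In a window of 10 kb on either side there were 8 peaks, more than in any of the 1000 random windows on 3R. With 100 kb on either side there were 15, and 39 of the 1000 random windows held as many. Among windows with 10 kb flanks on all arms and a like number of TSSs, 50 of 21526 held at least 8 peaks. That comparison was added after the data were seen. The whole pooled list lay at percentile 99.3, 94.3 and 84.1 of random windows with flanks of 10, 50 and 100 kb.

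**Figure D3:**
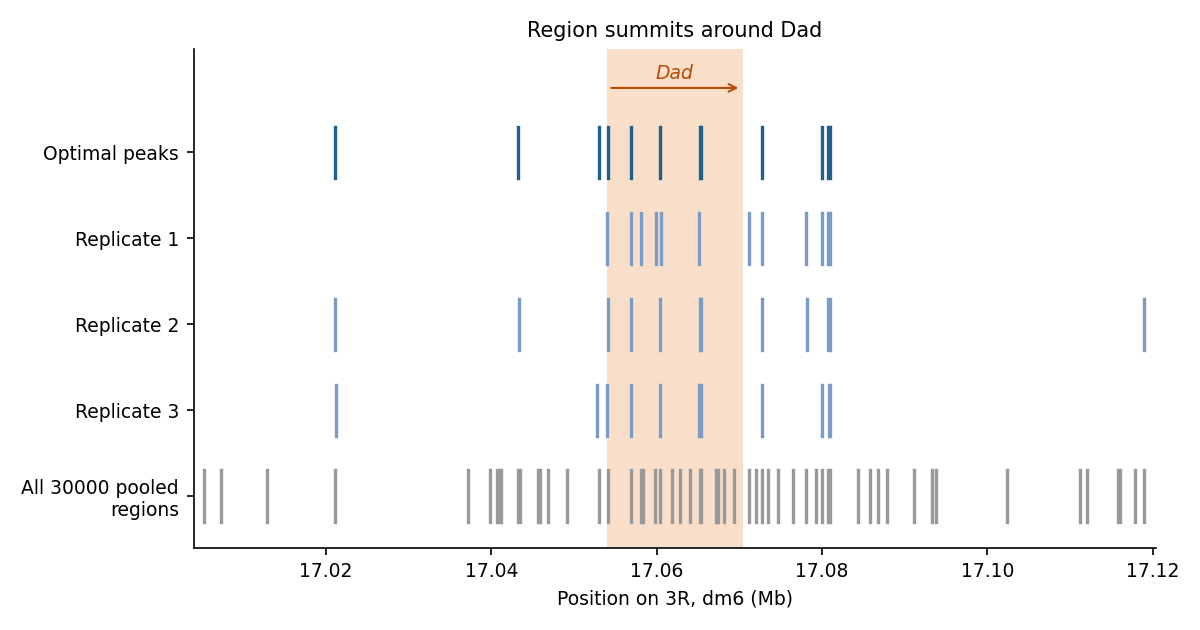
Summits of regions within 50 kb of Dad on 3R (dm6, position in Mb), with the 12 optimal peaks, the regions among the top 3392 of each replicate, and all regions of the pooled list. The shaded span is Dad, with the arrow giving its strand. Most optimal peaks recur at the same position in each replicate.

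The Ohler 7, DREF, BEAF-32 and CTCF motifs were more common at summits than in matched background, while a higher frequency of the Mad motif was not found. Windows of 100 bp on either side of the summit were compared with 3392 background regions of the pooled list matched for GC content and TSS proximity, and 6 of 20 motifs fixed beforehand were more frequent and 0 less frequent by Fisher's exact test. The promoter element Ohler 7 (CAGCNCTG) occurred in 6.60% of peaks against 3.51% (odds ratio 1.94, 95% interval 1.55 to 2.44, exact adjusted p = 1.29e-07). The DREF element (TATCGATA) occurred in 6.49% against 3.63% (1.84, 1.47 to 2.31, exact adjusted p = 5.78e-07), and the insulator protein motifs BEAF-32 (YATCGATA) in 9.11% against 5.60% (1.69, 1.40 to 2.04, adjusted p = 3.56e-07) and CTCF (AGRKGGCR) in 6.81% against 4.7% (1.47, 1.19 to 1.80, adjusted p = 0.00160). Every DREF match is also a BEAF-32 match, so these 2 calls are not separate. These 4 passed in each of 20 other random draws of the background, a check added after the data were seen. The DREF and BEAF-32 odds ratios above exceed those of all 20 draws, which were 1.36 to 1.67 (median 1.55) and 1.45 to 1.66 (median 1.6), so their size here is on the high side. The CTCF call was lost against unmatched background (odds ratio 1.16, exact adjusted p = 0.0695). The DREF and BEAF-32 calls were lost without replicate 2. With the 2391 regions shared by replicates 1 and 3 in place of the optimal peaks, a change of both replicates and list, the odds ratios were 1.29 and 1.20 (Fisher's exact test, adjusted p = 0.0976 and 0.129). Among the stronger 1696 peaks they were 1.28 and 1.27 (exact adjusted p = 0.228 and 0.179).

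Of the motifs of the Smad pathway, the Mad motif (GCCGNCG) occurred in 5.07% of peaks and 5.51% of background regions (odds ratio 0.916, 0.740 to 1.13, Fisher's exact test, adjusted p = 0.814). Its shuffled control gave 3.27% and 3.42%. The median odds ratio of the Mad motif over the 20 other draws was 0.850, with none past the threshold. Against unmatched background and flanks, which have a higher GC content than peaks, it was 0.371 and 0.473 (exact adjusted p = 5.10e-44 and 1.27e-18), and the shuffled control fell too, to 0.50 and 0.585 (exact adjusted p = 1.31e-13 and 1.48e-06). The Mad/Medea activating element, searched only as GGCGCCA, occurred in 3.07% against 1.98% (1.57, 1.15 to 2.14, exact adjusted p = 0.0206). The Brinker motif (TGGCGYY) occurred in 9.43% against 7.69% (1.25, 1.05 to 1.48, exact adjusted p = 0.0393). Every match of the activating element is, on the other strand, also a Brinker match, so these 2 calls are not separate. The element was in 104 peaks and 67 background regions, all within the 320 and 261 with a Brinker match. Both calls depended on the setting: the first passed in 14 and the second in 1 of the 20 other draws. Both were larger in windows of 50 bp, with odds ratios of 2.09 and 1.52 (exact adjusted p = 0.00414 and 0.00163), and were lost in windows of 250 bp, with 1.02 and 1.07 (exact adjusted p = 1 and 0.573). The activating element was also lost against unmatched background (1.01, exact adjusted p = 0.964), against flanks (1.28, exact adjusted p = 0.0864) and among the stronger 1696 peaks (1.33, exact adjusted p = 0.285). Brinker was lost among the stronger peaks and against flanks (1.18 and 0.993, exact adjusted p = 0.280 and 1), and passed below unmatched background (0.821, exact adjusted p = 0.00244). Without replicate 2, in its smaller set of regions, the odds ratios were 1.37 and 1.20 (exact adjusted p = 0.129 and 0.0976). The first also missed the threshold without replicate 3 (exact adjusted p = 0.0502) and the second without replicate 1 (adjusted p = 0.775). The silencer element bound by Mad, Medea and Schnurri (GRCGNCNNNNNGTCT) was found in 5 peaks and 3 background regions, and the palindromic Smad box (GTCTAGAC) in 2 and 3. The core promoter motifs M1BP and Ohler 6, the insulator motif Su(Hw), and the Zelda, Twist, Grainyhead, Pho, E-box and GAGA factor motifs did not pass. The GAGA factor result (odds ratio 1.29, exact adjusted p = 0.173) depended on the setting. It passed without replicates 1, 2 and 3 in turn (1.63, 1.62 and 1.49, exact adjusted p = 6.07e-04, 0.00163 and 0.0109), in windows of 250 bp (1.62, exact adjusted p = 2.92e-09) and in 6 of the 20 other draws. Against flanks of the same peaks it passed in the other direction (0.745, exact adjusted p = 0.00673), as did its shuffled control (0.480, exact adjusted p = 2.75e-04), so this fall is not particular to the motif. M1BP (0.934) passed below background without replicate 1 (0.604, exact adjusted p = 0.0170) and among the stronger 1696 peaks (0.564, exact adjusted p = 0.0356), and above it against unmatched background (2.41) and flanks (5.39). Above background, Ohler 6 passed against unmatched background (2.47) and flanks (2.98), Su(Hw) against flanks (3.35) and E-box in windows of 250 bp (1.31, exact adjusted p = 0.0176). Pho passed below unmatched background (0.779).

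**Figure D4:**
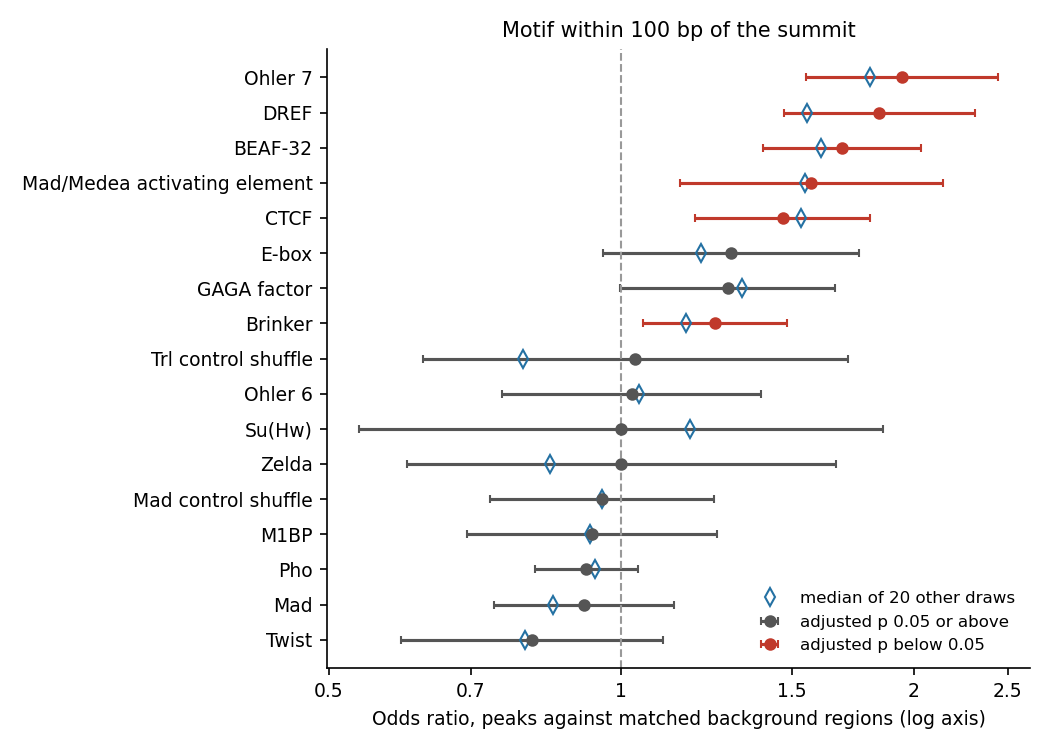
Odds ratio (log axis) of each motif present in at least 20 peaks, peaks against matched background regions, with 95% intervals. Diamonds are the medians of 20 other draws of the background. Ohler 7, DREF, BEAF-32 and CTCF lie above 1 in both, and Mad lies near 1.

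A scan of all 2080 6-mers found 76 more frequent and 64 less frequent at summits. The largest odds ratios among those in at least 5% of peaks belonged to ACAGTG (20.1% against 11.7%; 1.90, 1.66 to 2.17, exact adjusted p = 5.56e-18), CTACAC (9.38% against 5.45%; 1.79, 1.49 to 2.16, adjusted p = 2.31e-07) and ACCCTG (6.52% against 3.92%; 1.71, 1.37 to 2.13, adjusted p = 2.00e-04). ACACTG was in 21.6% of peaks against 13.9% (1.70, 1.49 to 1.92, exact adjusted p = 2.66e-13), and CGATAG, which overlaps the DREF and BEAF-32 elements, in 14.9% against 9.76% (1.61, 1.39 to 1.87, adjusted p = 9.46e-08). All p-values of the scan are from Fisher's exact test. The number that passed depended on the window, from 43 at 50 bp to 280 at 250 bp, against 140 in all at 100 bp.

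The same libraries placed on the older build dm3 gave 3225 optimal peaks covering 1192 kb, with a median signal of 125.2, and no coordinates were carried between the builds. There, all 3 replicates shared 57.6% of the peaks. The counts per arm were 614, 608, 646, 767, 10 and 580 on 2L, 2R, 3L, 3R, 4 and X, beside 636, 649, 681, 803, 11 and 612 on dm6.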

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

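No replicate was tested as an outlier, since 3 values in 1 group are too few, and no second group exists. The 3 patterns below are those a reader would most want to follow up. The tests of gene length with TSS number (a planned setting, turned to this explanation later), of promoter GC content, of promoter density around Dad and of other motif background draws were chosen after the results were seen, and the other 3 were written down before. The design gives a single group, so no biological explanation was tested for the first 2 patterns, and for the last 1 was tested, Mad/Medea sites.

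Peaks at promoters of highly transcribed genes. Gathering of reads at open, highly transcribed promoters whatever the antibody binds predicts an excess at ribosomal protein genes, and the ratio to genes of like length was 5.0. Gene length and TSS number as the whole account are argued against by a ratio of 3.78 within classes of both (exact adjusted p = 2.43e-29), and GC content by a ratio of 3.6 within deciles of GC at the TSS (exact adjusted p = 1.45e-25). Recovery of the tagged protein itself at these promoters stays open too, and a library from untagged embryos, not analysed here, would be needed to separate it from the first. The files hold no expression values, so transcription was taken from what is known of these genes.

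Regions over the Dad locus. Extra copies of the locus in the transgene would add reads around Dad unless the control, whose source is not given in the sources used here, carries them too, and in each replicate the number of top regions within 50 kb lay at or above percentile 98.1 of random windows. A high number of promoters nearby is argued against, because among 34541 windows with a number of TSSs within 20% of the 26 found here the optimal peaks lay at percentile 98.7. Regions below the top 3392 lay at percentile 80.5, 94.9 and 96.4 of these windows in replicates 1, 2 and 3, so an excess of weak regions within 50 kb is not clear. Within 10 kb they lay at 93.1, 99.8 and 98.9 of 21526 windows matched to the 7 TSSs there. Binding of the tagged protein to elements of Dad, a Dpp target gene, may give the same excess and stays open, since what flanking sequence the transgene carries is not given in the sources used here.

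Smad motifs at peaks. If Mad/Medea sites drew the tagged protein to its peaks, the Mad motif would be more frequent than in matched background, and its odds ratio was 0.916 with an interval from 0.740 to 1.13, which leaves both directions open. Lower values against flanks (0.473) and unmatched background (0.371) do not single out this motif, because the shuffled motif fell too (0.585 and 0.50). Chance in the draw of the background is not settled for the Mad/Medea activating element, which passed in 14 of 20 other draws with a median odds ratio of 1.55. The element had an odds ratio of 2.09 (1.34 to 3.26) in windows of 50 bp and 1.02 in windows of 250 bp. Draws with more than 1 matched region per peak were not made, and sites of weaker consensus were not searched.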

How the results depend on the processing

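The draws of other motif backgrounds were chosen after the data were seen; the other settings were planned. Promoter location kept its direction and side of the threshold under every alternative run. Optimal peaks around Dad lay at percentile 96.1 or above of random windows with flanks of 10, 50 and 100 kb. The number of called gene lists was 3 in the main run and in every alternative but the gene body rule, which gave 4. The share of TSS peaks ranged from 52.2% (250 bp) to 70.5% (1000 bp) and from 61.3% to 63.7% without 1 replicate. Ribosomal protein and receptor genes passed in every setting and the list of translation, cytoskeleton and glycolysis genes in all but the gene body rule (ratio 1.5). That rule also brought segmentation genes (0.377) and tRNA genes (0.766) past the threshold, below prediction. Replicate support depended on the rule: 44.0% with reciprocal overlap of 50%, 48.5% with summits within 100 bp, 86.5% with double the regions, 99.2% with all regions, and 65.2% to 68.7% without 1 replicate, where fewer lists must agree. Rank agreement was 0.638 to 0.661 without 1 replicate. The signal difference between TSS and other peaks turned to −0.024 at 250 bp and passed the test with the signal of replicate 1 (3.80) and of replicate 3 (2.20); the cause was not tested.

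Motif results moved most. Against unmatched background 10 motifs and 1566 6-mers passed, and against flanks of the same peaks 11 and 1327. The motif totals count both directions: Mad and both shuffled controls passed below background in each case. So did Brinker and Pho against unmatched background and GAGA factor against flanks. The GC content of these backgrounds was 46.2% and 43.5%, against 38.6% at peaks, and the Brinker odds ratio fell to 0.821 and 0.993. The 1696 stronger peaks gave 3 motifs and 80 6-mers with fewer sequences tested. Windows of 50 and 250 bp gave 43 and 280 6-mers. Without 1 replicate, 3 to 7 motifs and 80 to 147 6-mers passed. The 20 other draws gave 4 to 6 motifs, median 5. Over all alternatives, single motifs kept their call or lack of one in 123 cases, gained one in 20 and lost one in 15. A motif called in the main run changed direction in 2, both Brinker and 1 of them past the threshold. Some gained calls had also turned direction: GAGA factor (1.29 to 0.745 against flanks) and M1BP (0.934 to 2.41 against unmatched background and 5.39 against flanks). Gene lists kept, gained and lost a call in 177, 2 and 1 cases, and no called list changed direction. Lists without a call did, such as Notch (2.15 to 0.428 without replicate 2) and the Activin branch (0.634 to 1.64 with a TSS window of 1000 bp). Depth is unknown, so what it limits was not measured.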

Other observations

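All tests in this part were chosen after the data were seen. Because 2 mitochondrial ribosomal protein genes were nearest to peaks among the 25 strongest, 20 further gene families were examined by the same exact permutation test within length deciles, with adjustment over these 20. Families were found by the start of the gene symbol, and 28 genes of other families that share it were left out after the first results, which changed no call. Of the 20, 3 had more promoter peaks than predicted and 3 fewer. Mitochondrial ribosomal proteins had 25 of 73 (34.2%, Wilson 95% interval 24.4 to 45.7, 11.1% predicted, ratio 3.08, exact adjusted p = 3.16e-06), with a replicate ratio of 2.95 ± 0.0756 (SD, n = 3). Their strongest were mRpS10 (952.3) and mRpS23 (910.9), whose peaks are those listed above for the divergent neighbours Art3 and CenG1A, then mRpL41 (859.5) and mRpL23 (739.2). Translation initiation factors had 17 of 44 (38.6%, 19.2% predicted, ratio 2.01, exact adjusted p = 0.0153, replicate ratio 1.83 ± 0.191, SD, n = 3). The strongest was eIF6 (2R, 23850238 to 23850543, signal 712.5), a peak that the gene body rule also counted for the BMP ligand gene gbb. RNA polymerase subunits had 10 of 29 (34.5%, 15.3% predicted, ratio 2.26), close to the threshold (exact adjusted p = 0.0487, and 0.0322 with PolrMT and Polr2M kept), led by Polr2H (326.1) and Polr2F (310.9). Their replicate ratio was 1.99 ± 0.551 (SD, n = 3), with 1.38, 2.47 and 2.11 in replicates 1, 2 and 3.

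Other families that most cells use did not pass, and they lay on both sides of the prediction. Rab GTPases had 11 of 28 (ratio 2.07, exact adjusted p = 0.0519), Mediator 8 of 25 (1.99, exact adjusted p = 0.153), Sm and LSm proteins 3 of 9 (3.40, exact adjusted p = 0.179) and general transcription factors 3 of 9 (2.21, exact adjusted p = 0.400). The vacuolar ATPase had 9 of 33 (1.58) and NADH dehydrogenase 9 of 40 (1.61), both with an exact adjusted p of 0.302. Nearer to prediction, TBP-associated factors had 3 of 15 (1.22) and cytochrome oxidase with complex III 4 of 25 (1.26), proteasome subunits had 8 of 48 (16.7%, 15.1% predicted, exact adjusted p = 1) and aminoacyl-tRNA synthetases 7 of 32 (21.9%, 20.9% predicted, exact adjusted p = 1). Below prediction were histones with 2.61% of genes (His2Av, His3.3A and His3.3B, 7.56% predicted, ratio 0.345, exact adjusted p = 0.0987), and with an exact adjusted p of 1 each the CCT chaperonin with 1 of 8 (0.609) and Mcm and Orc genes with 2 of 12 (0.853). Whether the histone genes without a peak are repeated copies, where reads may not be placed uniquely, was not examined. The permutation test also treats each gene as separate, so no conclusion is drawn from the histone share. Of the families that passed below prediction, cuticle proteins had 0 of 94 (Wilson upper limit 3.93%, 12.5% predicted, exact adjusted p = 3.41e-05). Cytochrome P450 genes had 1 of 83, Cyp6u1 (ratio 0.0622, exact adjusted p = 5.91e-06), and ionotropic receptors 1 of 60, Ir60e (ratio 0.0868, exact adjusted p = 3.81e-04). Digestive serine proteases had 0 of 28 (10.3% predicted) and did not pass (exact adjusted p = 0.179). Among Dpp target genes, the strong peak within 5 kb of bam (3R, 25247389 to 25247673, signal 613.5) is the promoter peak of RpS27.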
